A study of Escherichia coli str. K-12 substr. MG1655 with 25 samples.

How the data were processed

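The deposited tables held whole-number counts per gene, one column per library, and per the labels they came from reads basecalled with CASAVA 1.8 and aligned with Bowtie2 2.1.0 by the authors. The authors' counting of ribosome profiling and irCLIP reads gave 4294 genes, and the tRNA table gave 50 tRNAs. Which genome build the authors aligned to was not stated, so no coordinate is given and the reference name table served only for gene names, locus tags and gene order. Of the 4294 genes, 4283 matched a locus tag of the name table and 11 did not. The length column equalled the annotated number of codons for 4076 genes in irCLIP and that number plus 5 in ribosome profiling, so it was read as a length in codons. No gene was at 0 in every library, and 131 were pseudogenes.

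Groups, tests, gene lists and alternatives were chosen before the data were examined, apart from 4 gene lists (anaerobic respiration and fermentation; threonine, lysine and arginine degradation; iron acquisition; aerobic respiration and lactate), the comparisons without 2 doubted libraries and the tests said in the closing section to be chosen later. Libraries were grouped by genotype, drug and dose as labelled. No label says that replicates came from separate cultures, so a p-value here measures only the spread between these samples. Counts of duplicates differed beyond sampling noise in each of 5 groups, with chi-square over degrees of freedom of 88.3 (chloramphenicol footprints), 1358 (capreomycin 2000 footprints), 96 (RNC tRNA), 123 (chloramphenicol irCLIP) and 22.6 (capreomycin irCLIP), and Spearman correlations of 0.995, 0.939, 0.931, 0.966 and 0.969. No pair was therefore a copy.

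Each comparison with a test used the edgeR 4.0.16 quasi-likelihood F-test in R 4.3.3 (robust fit, two-sided), TMM scaling, and the expression filter of edgeR (count of 10, total of 15). Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called at an adjusted p under 0.05. Only the libraries compared entered a fit, except that comparisons with an unreplicated wild-type group used all 12 wild-type footprint libraries with 1 term per group, where the spread came from the 2 duplicated groups. Mutant comparisons pooled both drugs with drug as a term. The comparison of irCLIP with footprints had drug as a term, and interactions were fitted in a single model. Values are log2 fold changes with the standard error (SE) of the fit; levels are CPM on library totals TMM-scaled within an assay, or over both assays where said, with the standard deviation (SD) over libraries of a group, except that the levels of the 24 neighbouring genes, lacZ, fliC and malK are CPM on unscaled totals. The tRNA comparison kept tRNAs with 10 counts summed over libraries, and it has 1 residual degree of freedom. Shares of single tRNAs carry exact binomial intervals, and floors were set at 3 counts; both cover counting error only.

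Named genes were those with an adjusted p under 0.05, a mean CPM of at least 20 and every library of the smaller group on the same side, up to 8 per direction by log2 fold change. Where none passed, up to 3 per direction with the smallest p are named as not passing. For lists that passed, up to 4 members with the smallest p could be named, and 2 otherwise. Pairs of single libraries had no test: genes with at least 100 counts summed and 10 in each library were named by log2 ratio (prior count of 2), and a log2 ratio of 1 was the threshold for counting. Median ratios of lists were set against random lists matched on expression.

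The 23 fixed lists and the 4 later ones were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. Within a comparison, Benjamini-Hochberg adjustment ran over the fixed lists and over the later lists apart. Lists under 5 tested members were left out. The later lists were drawn up with these data in view, so their p-values are no independent evidence. List members were also adjusted over the list alone. Alternatives tried were DESeq2 size factors within edgeR, no low-count filter, the DESeq2 1.42.0 Wald test, each library left out in turn, each drug alone for the mutant comparisons, the replicate number as a block, 1000 summed counts and total-count scaling for single libraries, and leaving out the 2 doubted libraries. For a single mutant, the fit for 1 drug kept the 10 libraries with 1 term per group, so 1 mutant library stood against 2 of wild type. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15. Sequence features near start codons (anti-Shine-Dalgarno pairing, A+U share, folding) were not run, because no genome sequence was used here. Alternatives for normalized values did not apply to counts.

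The code was tested on simulated counts, drawn from a negative binomial with the fitted mean levels and dispersions of each comparison: a sample of genes was raised or lowered by 2-, 4- and 8-fold and the share called was recorded. For capreomycin 2000 against chloramphenicol footprints the share was 4.62%, 50% and 96.9%. The mutant comparison of the same drugs recovered 1.52%, 39.1% and 84.8%, and the mutants against wild type 9.38%, 56.9% and 84.4%. For rpsA1, rpsAdelta6 and rpsAdelta56 against wild type the shares were 1.49%, 50.8% and 71.2%, then 4.48%, 40.9% and 86.2%, then 1.49%, 45.5% and 75.4%. The difference between rpsAdelta56 and rpsAdelta6 recovered 3.08%, 20.9% and 68.2%, and the interaction of mutant and drug recovered 0% at all 3 sizes. Chloramphenicol against no drug recovered 1.49%, 16.7% and 65.2%. Capreomycin 2000 recovered 0%, 22.7% and 66.7% against no drug, 0%, 20.9% and 61.5% against viomycin 2000, and 0%, 37.9% and 80.3% against 200. The irCLIP drug comparison recovered 28.8%, 85.1% and 98.5%, irCLIP against footprints 2.99%, 78.1% and 89.1%, and its interaction with drug 3.03%, 24.6% and 66.2%. The tRNA comparison recovered 75%, 100% and 100%, which are only 3 of 4, 3 of 3 and 3 of 3 tRNAs. In the real data edgeR did not call tRNA-Asn(GTT), higher by 4.48-fold and 6.38-fold (adjusted p = 0.0593). The tRNA shares therefore do not describe the power of that test. A count of 0 leaves differences open at every size with a low share, which always includes 2-fold. It includes 4-fold differences in chloramphenicol against no drug (16.7%) and in the drug comparison of the mutants (39.1%). Many 4-fold differences were also missed for rpsA1 (50.8% recovered) and for the mutants against wild type (56.9%). For the interaction of mutant and drug even 8-fold differences stay open.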

Results

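Ribosome footprints were counted in 18 Escherichia coli libraries, irCLIP reads in 4 and tRNA reads in 3. The wild-type footprint libraries comprised 1 without drug, 1 each with capreomycin, viomycin or spectinomycin at 200 micrograms per ml, 1 each with viomycin or spectinomycin at 2000, 1 with blasticidin, 1 with linezolid, 2 with chloramphenicol and 2 with capreomycin at 2000. Capreomycin and viomycin are related cyclic peptides of the tuberactinomycin family. The mutants labelled rpsA1, rpsAdelta6 and rpsAdelta56 each had 1 library in chloramphenicol and 1 in capreomycin 2000. The irCLIP libraries were 2 with chloramphenicol and 2 with capreomycin, and the labels do not name the crosslinked protein, while the series title names S1. The tRNA libraries were labelled RNC1, RNC2 and input. Per the labels' protocols, footprints were made with micrococcal nuclease and rRNA depletion, irCLIP used ultraviolet crosslinking and nuclease on beads, and tRNAs were deacylated. Totals ran from 1300311 (spectinomycin 200) to 21434776 (capreomycin 2000, first library) counts for footprints, a 16.5-fold range. The irCLIP totals were 3810209 and 4410944 with chloramphenicol and 1386641 and 1270616 with capreomycin. RNC1, RNC2 and input tRNA held 35593, 115113 and 5252209 counts.

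The other footprint totals were 13983916 (no drug), 15844559 (capreomycin 200), 4828625 (viomycin 200), 15632505 (blasticidin), 2409419 (spectinomycin 2000), 1649372 (linezolid), 1821987 (viomycin 2000), 11767343 and 14038982 (chloramphenicol) and 18084195 (capreomycin 2000, second library). In chloramphenicol and capreomycin the mutants had 16615230 and 5400627 (rpsA1), 5721787 and 12088216 (rpsAdelta6) and 3265456 and 8731830 (rpsAdelta56) counts. The median count per gene in a footprint library lay between 19 and 423.5.

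The gene for ribosomal protein S1, rpsA, was read in every library. Its level was 6080 CPM without drug, 3292 in capreomycin 200, 5924 in viomycin 200, 2654 in spectinomycin 200, 3966 in blasticidin, 8247 in spectinomycin 2000, 8551 in linezolid and 5136 in viomycin 2000. Chloramphenicol gave 2863 and 3490 CPM and capreomycin 2000 gave 10268 and 3178. In chloramphenicol and capreomycin the levels were 2490 and 3950 CPM in rpsA1, 8099 and 14204 in rpsAdelta6, and 4683 and 5936 in rpsAdelta56. The irCLIP levels, scaled within irCLIP and so not on the footprint scale, were 30302 and 63541 CPM with chloramphenicol and 22636 and 34834 with capreomycin. Gene-level counts cannot check a truncation or an insertion, so the genotypes rest on the labels. No comparison of genotypes called rpsA, with log2 fold changes against wild type of -0.57 (SE 0.48, adjusted p = 1) in rpsA1, 1.15 (SE 0.45, adjusted p = 0.136) in rpsAdelta6 and 0.19 (SE 0.46, adjusted p = 0.80) in rpsAdelta56. The last value was -0.11 without the rpsAdelta56 chloramphenicol library, -0.02 without the second capreomycin 2000 library and -0.19 within capreomycin. Without the first capreomycin 2000 library the rpsAdelta6 value was 1.75 and passed (adjusted p = 0.0335).

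A group of 24 neighbouring genes told the strains apart. It held 17 genes from yahI to cynS, which include propionate and cyanate metabolism, and 7 from mhpR to mhpE, which degrade phenylpropionate. Their summed level was 0 to 1.14 CPM in 11 libraries labelled wild type and 124 to 185 CPM in 5 labelled as mutants. The library labelled wild-type capreomycin 2000 replicate 2 had 177 CPM and the library labelled rpsA1 capreomycin 5.18. The gene for beta-galactosidase, lacZ, ran the other way, with 694 to 4152 CPM in the 11 libraries and 21.5 to 203 in the 5, against 115 CPM in the library labelled wild-type capreomycin 2000 replicate 2 and 4954 in the library labelled rpsA1 capreomycin. Both libraries were kept under their labels. Wild-type and mutant libraries thus differed at loci other than rpsA. In each comparison of mutants with wild type below, an effect of rpsA therefore cannot be told apart from an effect of strain background.

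**Figure D1:**
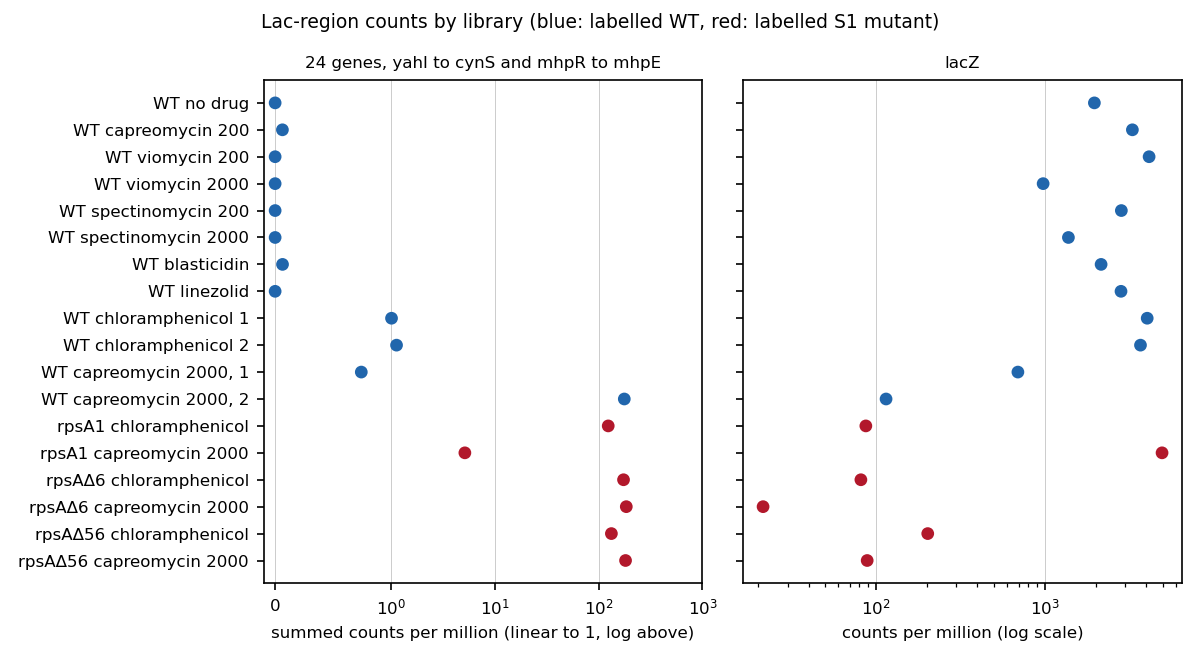
Summed level of the 24 genes (yahI to cynS and mhpR to mhpE) and level of lacZ in 18 footprint libraries. Libraries labelled wild type are blue and libraries labelled as mutants are red.

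In wild type, footprints of lactate and respiratory genes were higher and those of nitrate, lysine and threonine genes lower in the capreomycin 2000 than in the chloramphenicol libraries (2 each). The lactate utilisation genes lldR and lldP rose by log2 fold changes of 5.31 (SE 0.26) and 4.79 (SE 0.34), lldR from 3.57 (SD 0.037) to 141 (SD 33.2) CPM. The respiratory genes mqo, cyoB and sdhB, for malate oxidation, a terminal oxidase and succinate dehydrogenase, rose by 4.62 (SE 0.50), 4.37 (SE 0.31) and 3.99 (SE 0.22), and putA, for proline oxidation, rose by 4.42 (SE 0.21). The lysine decarboxylase gene cadA fell from 1541 (SD 840) to 5.30 (SD 2.22) CPM, a log2 fold change of -8.17 (SE 0.72). Threonine degradation and nitrate or nitrite respiration genes fell as well, among them tdcD (-7.22, SE 0.52), nrfD (-7.14, SE 0.34), narH (-7.13, SE 0.50) and narI (-6.90, SE 0.40). The edgeR quasi-likelihood test called 449 of 3851 genes, 153 higher and 296 lower, with a smallest adjusted p = 0.0165, and DESeq2 called 1138. Without the first or the second chloramphenicol library 0 genes passed, with a smallest adjusted p for lldR of 0.199 and 0.29, and 1893 and 1672 passed without the first and the second capreomycin library. The value for rpsA was 1.08 (SE 0.64, adjusted p = 0.285), and 1.69 (adjusted p = 0.00137) without the second and 0.0121 (adjusted p = 0.968) without the first capreomycin library, so it rests on the first.

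Among the fixed gene lists of that comparison, RpoS, hibernation and glycolysis genes were lower and TCA cycle genes higher. Of 24 tested RpoS general stress genes 15 fell and 9 did not pass (20 fell when adjusted over the list alone), including tktB (-2.01, SE 0.18), hdeB (-2.57, SE 0.27) and dps (-1.84, SE 0.20), and the list passed camera at an adjusted p = 1.47e-10. With an estimated correlation the adjusted p = 0.665 for this list, and it was 0.665 as well for ribosome hibernation, glycolysis and the TCA cycle. Of 8 hibernation genes, which hold ribosomes inactive, 5 fell (6 adjusted over the list alone), with sra at -1.55 (SE 0.15) and rmf at -1.81 (SE 0.27). Glycolysis had 7 of 17 lower (12 adjusted over the list alone), among them tpiA (-2.01, SE 0.27) and pfkA (-2.59, SE 0.35). In the TCA cycle 6 of 17 rose and 1 fell (12 and 1 adjusted over the list alone), led by sdhB, sdhA (3.70, SE 0.22) and sdhC (3.47, SE 0.30). Camera gave adjusted p = 9.31e-04, 2.69e-06 and 6.11e-05 for these 3 lists. Of 28 toxin-antitoxin genes 4 rose (4 adjusted over the list alone), including hokD (3.42, SE 0.49) and higB (2.13, SE 0.33), at a list adjusted p = 0.00671, or 0.836 with an estimated correlation. Leader peptides, which set transcription of amino acid operons, had 4 of 10 higher (6 adjusted over the list alone), with ivbL at 1.76 (SE 0.24) and hisL at 1.58 (SE 0.23), at a list adjusted p = 0.0273, or 0.834 with an estimated correlation.

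Ribosomal protein and flagellar genes depended on which capreomycin libraries were kept. For the large subunit 0 of 33 passed (0 adjusted over the list alone), though the list median was 1.07 and the list passed at adjusted p = 6.11e-05, or 0.862 with an estimated correlation. For the small subunit 2 of 20 rose (3 adjusted over the list alone), rpsR (1.40, SE 0.23) and rpsN (1.08, SE 0.20), at a list adjusted p = 5.34e-04, or 0.837 with an estimated correlation. Without the library labelled wild-type capreomycin 2000 replicate 2, whose summed level of the 24 genes was 177 CPM, 1 capreomycin library was left. The large and small subunit medians were then 1.4 and 1.3. The second capreomycin library against the first had median log2 ratios of -1.04 and -0.828 for the large and small subunit. All 39 tested motility genes had positive values with a median of 5.15, none passed (0 adjusted over the list alone), and the list passed camera at 7.36e-04, or an adjusted p = 0.866 with an estimated correlation. Without the library labelled replicate 2 the motility median was -0.155. Between the 2 capreomycin libraries the second was higher by 219-fold for the flagellin gene fliC and 230-fold for the maltose transport gene malK, and its heat shock genes had a median log2 ratio of 3.97.

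Lists drawn up after the data had been seen held many of the genes called. Of 72 anaerobic respiration and fermentation genes 48 fell (60 adjusted over the list alone) with a median of -3.21, including narJ (-6.48, SE 0.30) and hypE (-4.81, SE 0.31). Threonine, lysine and arginine degradation had 8 of 15 lower (12 adjusted over the list alone), and aerobic respiration and lactate had 15 of 33 higher (19 adjusted over the list alone). Of 36 iron acquisition genes 5 rose (14 adjusted over the list alone), such as efeO (4.32, SE 0.49) and tonB (3.21, SE 0.48). Camera gave adjusted p = 6.62e-29, 1.67e-07, 2.37e-12 and 4.23e-09 for the 4 lists in this order, and adjusted p = 0.266, 0.266, 0.074 and 0.358 with an estimated correlation. Because the lists were chosen after these libraries had been seen, the p-values restate that choice and do not test it. Without the library labelled wild-type capreomycin 2000 replicate 2 the iron median moved from 3.98 to 2.1, with 1 capreomycin 2000 library left. A score of anaerobic genes, the mean of centred log2 levels, was 0.903 to 1.44 in the other 10 wild-type libraries and -1.21 and -1.95 in the 2 capreomycin 2000 libraries. It was 1.55 in rpsA1, -2.55 in rpsAdelta6 and -1.64 in rpsAdelta56 with chloramphenicol, and -0.846, -2.64 and -3.08 with capreomycin.

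**Figure D2:**
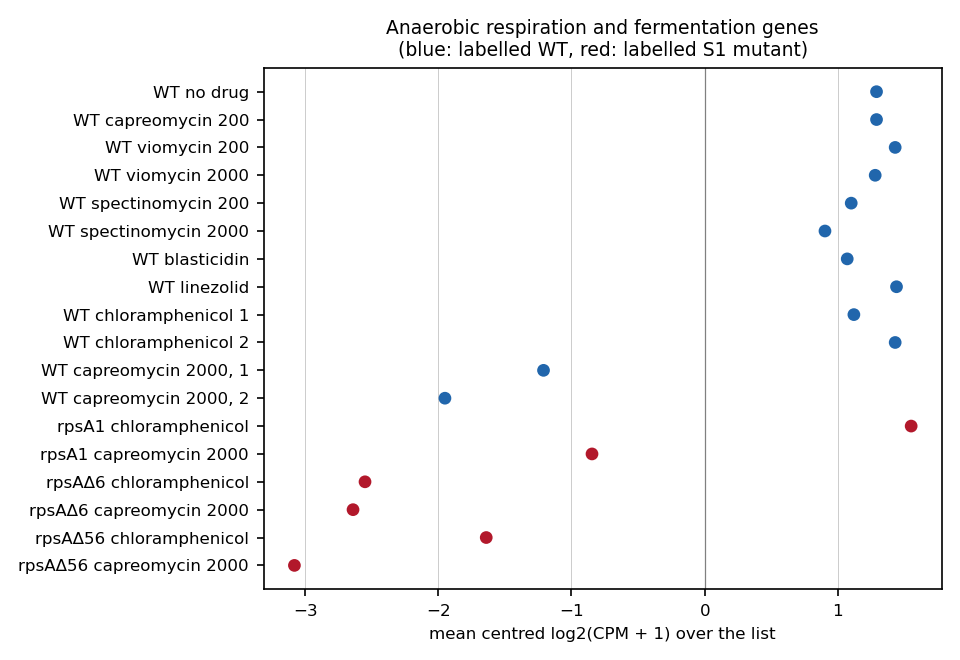
Mean centred log2 level of anaerobic respiration and fermentation genes in each footprint library.

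Against no drug, the same 2 capreomycin 2000 libraries were higher for lactate genes and lower for nitrate genes. The genes lldR and lldP rose by 7.80 (SE 0.44, adjusted p = 0.0185) and 7.75 (SE 0.54), sdhB by 4.93 (SE 0.28), and mglC, for galactose transport, by 6.15 (SE 0.26). The nitrate reductase genes narH (-8.99, SE 0.58), narI (-8.52, SE 0.45) and narJ (-7.90, SE 0.33) fell. In the TCA cycle 6 of 17 rose (14 higher and 1 lower adjusted over the list alone), for example sdhA at 4.75 (SE 0.27), and 5 of 17 glycolysis genes fell (13 adjusted over the list alone), for example tpiA (-2.25, SE 0.31). Of 25 RpoS genes 8 fell (1 higher and 14 lower adjusted over the list alone), such as gadC (-2.21, SE 0.19) and hdeD (-3.06, SE 0.27). The lists passed at adjusted p = 3.89e-06, 8.17e-08 and 1.75e-06, and each at adjusted p = 0.696 with an estimated correlation. Of the RNA decay genes 3 fell (5 adjusted over the list alone), among them rhlE (-2.54, SE 0.19), with a list adjusted p = 0.00572, or 0.696 with an estimated correlation. The test called 258 of 4046 genes, 88 higher and 170 lower, and DESeq2 called 414. With both capreomycin libraries 0 heat shock and 0 large subunit genes passed, and the motility median was 3.43. Without the library labelled wild-type capreomycin 2000 replicate 2 (177 CPM for the 24 genes), 1 capreomycin 2000 library was left. The heat shock, large subunit and motility medians were then -3.11, 0.8 and -0.893. No drug had 1 library, taken to vary like the duplicated groups. Without either chloramphenicol library 0 genes passed, which changes only the spread, and 2015 and 1706 passed without the first and the second capreomycin library. The value for rpsA turned from 0.07 to -1.01 (adjusted p = 0.0246) without the first capreomycin library.

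At the same dose of 2000, capreomycin (2 libraries) was set against the related peptide viomycin (1 library, taken to vary like the duplicated groups). Capreomycin was above viomycin for lldD (6.29, SE 0.66), gltA (4.88, SE 0.84), mglC (4.73, SE 0.25) and feoA (4.27, SE 0.74), which serve lactate oxidation, citrate synthesis, galactose and iron uptake. It was below viomycin for narJ (-8.44, SE 0.34), hcp (-7.46, SE 0.54), napG (-6.14, SE 0.47) and hypE (-5.79, SE 0.35), which serve nitrate, nitric oxide and hydrogen metabolism. Oxidative stress genes had 4 of 21 higher and 1 lower (11 and 1 adjusted over the list alone), including grxA (3.55, SE 0.26) and trxC (2.25, SE 0.24). In the TCA cycle 10 of 17 were higher (15 and 1 lower adjusted over the list alone), among them sdhA (3.38, SE 0.25). Toxin-antitoxin genes had 6 of 30 higher (9 adjusted over the list alone), such as dinJ (1.90, SE 0.21) and yafN (2.13, SE 0.27), and leader peptides had 3 higher (6 adjusted over the list alone), with trpL at 7.29 (SE 1.33). These 4 lists passed at adjusted p = 0.00222, 1.95e-06, 0.0263 and 0.0152, and all had an adjusted p = 0.903 with an estimated correlation. The secretion gene tatB (-2.44, SE 0.19) was lower, and sulA (2.33, SE 0.27) of the SOS response was higher. The test called 664 of 4046 genes, 282 higher and 382 lower (smallest adjusted p for named genes 0.0216), and 1809 and 1733 without the first and the second capreomycin library. Without the first or the second chloramphenicol library 0 passed. With both capreomycin libraries 0 heat shock and 0 large subunit genes passed, and the motility median was 5.64. Without the library labelled wild-type capreomycin 2000 replicate 2 (177 CPM for the 24 genes), 1 library stood on each side. The heat shock, large subunit and motility medians were then -2.65, 1.1 and 0.774. The median of all genes was 0.161 with TMM and 0.0286 with DESeq2 size factors. The value for rpsA was 0.47 (SE 0.79, adjusted p = 0.688), -0.61 without the first capreomycin library and 1.08 (adjusted p = 0.0241) without the second.

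Capreomycin at 2000 (2 libraries) was set against the 1 library at 200. From 200 to 2000, hdeB (-5.65, SE 0.37), gadA (-5.13, SE 0.33) and gadC (-4.78, SE 0.19) fell, and so did the hibernation genes rmf (-3.12, SE 0.31) and sra (-2.74, SE 0.19). Threonine degradation genes tdcF (-9.79, SE 1.32) and tdcE (-8.91, SE 1.01) and the hydrogenase regulator gene hycA (-9.64, SE 0.93) also fell, with tdcE at 25317 CPM at 200 and 51.5 (SD 22.6) at 2000. The gene sodA, for superoxide dismutase, rose by 5.34 (SE 0.70, adjusted p = 0.032), lldR by 8.21 (SE 0.44, adjusted p = 0.0158) and cyoE by 5.04 (SE 0.24). Of 25 RpoS genes 14 fell (1 higher and 18 lower adjusted over the list alone) and of 8 hibernation genes 4 fell (6 adjusted over the list alone), at list adjusted p = 1.01e-12 and 1.24e-04, both at adjusted p = 0.686 with an estimated correlation. The test called 367 genes, 116 higher and 251 lower, and DESeq2 470. Without either chloramphenicol library 0 passed, and 1889 and 1719 passed without the first and the second capreomycin library. With both capreomycin 2000 libraries 0 heat shock, 0 motility and 0 large subunit genes passed. Without the library labelled wild-type capreomycin 2000 replicate 2 (177 CPM for the 24 genes), 1 library stood at each dose. The heat shock, motility and large subunit medians were then -2.11, -1.35 and 1.71. The lone library at 200 was taken to vary like the duplicated groups. For rpsA the value was 1.06 (SE 0.81, adjusted p = 0.422), -0.01 without the first capreomycin library and 1.67 (adjusted p = 0.00502) without the second.

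Chloramphenicol against no drug gave no gene that passed. The smallest p fell on sialic acid and galactose genes above, nanK (3.94, SE 0.28), mglC (3.55, SE 0.23) and nanQ (3.53, SE 0.24), and on formate hydrogenlyase genes below, hydN (-5.05, SE 0.38), hycC (-3.52, SE 0.24) and hycE (-2.78, SE 0.18), all at an adjusted p = 0.0894. Of 47 tryptophanase and sugar catabolism genes 0 passed (19 higher adjusted over the list alone), and the list passed camera at an adjusted p = 1.38e-07 with a median of 1.31, or 0.719 with an estimated correlation. Aminoacyl-tRNA synthetases and translation factors had medians of -0.773 and -0.804 with none passing (0 and 2 lower adjusted over the list alone), at list adjusted p = 7.20e-06 and 2.63e-05, both at adjusted p = 0.719 with an estimated correlation. The edgeR test called 0 of 4046 genes with 977 at an unadjusted p under 0.05, and DESeq2 called 185. Without the first and the second capreomycin 2000 library, which serve only the spread, 1531 and 1530 genes passed.

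The other drugs each had 1 library and were set against the 1 library without drug, with no replicate check and no p. The hydroxyisourate hydrolase gene hiuH was higher by 125-fold in spectinomycin 200 and 390-fold in blasticidin, and the methionine sulfoxide reductase gene msrP by 70.2-fold and 141-fold. In the same libraries the median log2 ratio of RpoS genes was 2.61 and 3.15 (percentile 100 for both among random lists matched on expression) and that of heat shock genes -1.99 and -2.01 (percentile 0 for both). The nitrite gene nirC and the fructose gene fruK were lower by 43.5-fold and 32.6-fold in capreomycin 200, 51.7-fold and 25.5-fold in viomycin 200, 123-fold and 47.1-fold in spectinomycin 200, and 483-fold and 333-fold in blasticidin. Linezolid had yhjX higher by 111-fold and malM by 52.7-fold, and its ribosomal protein medians were 1.21 (small subunit, percentile 99.96) and 1.07 (large subunit, percentile 100). Viomycin 200 also had malM higher, by 48-fold, and viomycin 2000 had dinQ higher by 85.5-fold and trmD by 23-fold. The motility gene flgE was lower by 18.8-fold in viomycin 2000, where RpoS genes had a median of -1.35 (percentile 0). Spectinomycin 2000 was closest to no drug, with yhjX higher by 37.2-fold and tdcF lower by 17.1-fold. Genes with a log2 ratio of at least 1 in size numbered 833 of 3036 in capreomycin 200, 536 of 2767 in viomycin 200, 875 of 2701 in viomycin 2000, 945 of 2674 in spectinomycin 200, 225 of 2660 in spectinomycin 2000, 1057 of 3042 in blasticidin and 540 of 2634 in linezolid. The 2 chloramphenicol libraries differed by that much in 38 of 2983 genes and the 2 capreomycin 2000 libraries in 517 of 3322. Between the 2 chloramphenicol libraries the large subunit median was -0.267 (percentile 0) and the RpoS median 0.178 (percentile 99.92). An extreme percentile therefore does not set a drug apart from the spread between libraries of 1 label.

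At the matched dose of 200, the capreomycin and viomycin libraries were close, with 255 of 2875 genes at a log2 ratio of at least 1 in size. The lysine decarboxylase genes cadA and cadB were higher with capreomycin by 17.4-fold and 17.1-fold, and yhjX and malM were lower by 13.6-fold and 10.9-fold. Capreomycin had a higher median for RpoS genes (0.954, percentile 100) and a lower median for large subunit ribosomal proteins (-0.753, percentile 0). Libraries of 1 label also reached such percentiles. The large subunit median was -0.267 (percentile 0) between the chloramphenicol libraries and -1.04 (percentile 0) between the capreomycin 2000 libraries. For RpoS genes it was 0.178 (percentile 99.92) and -0.0507 (percentile 36.78). From viomycin 200 to 2000, dinQ was higher by 66.4-fold and napF by 46.8-fold, while dsdA was lower by 97.7-fold and lamB by 31.3-fold, with 852 of 2312 genes past the threshold. From spectinomycin 200 to 2000, nirC was higher by 108-fold and the hibernation gene rmf lower by 139-fold, with 732 of 1914 genes past it. These are comparisons of those libraries only.

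In the S1 mutants, capreomycin against chloramphenicol (3 libraries each, genotype as a term) gave no gene that passed. The threonine dehydratase gene tdcB was at -4.71 (SE 0.46, adjusted p = 0.267), the dimethyl sulfoxide reductase gene dmsC at -2.64 (SE 0.46, adjusted p = 0.376) and the phosphate transport gene pstA at 2.37 (SE 0.32, adjusted p = 0.376). Of 46 tryptophanase and sugar genes 0 passed (0 adjusted over the list alone) with a median of -1.34. That list passed camera at an adjusted p = 3.81e-17, and large subunit proteins at 4.41e-06 with a median of 0.618 and 0 of 33 passing (0 adjusted over the list alone), both at adjusted p = 0.945 with an estimated correlation. The edgeR test called 0 of 3678 genes with 390 at an unadjusted p under 0.05, and DESeq2 called 120. Without the library labelled rpsA1 capreomycin, whose summed level of the 24 genes was 5.18 CPM, 57 genes passed, and 1 passed without rpsA1 chloramphenicol. Without the former library the tryptophanase and large subunit medians were -1.52 and 0.445, both lists at adjusted p = 0.847 with an estimated correlation. In all 10 splits of the 6 libraries 0 genes were called, too few to judge. The capreomycin effect in mutants and in wild type, which share no library, had a Spearman correlation of 0.337 over 3643 genes, and 345 of 436 genes called in wild type (79.1%) had the same sign in the mutants.

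The 3 mutants together against wild type (6 and 4 libraries, drug as a term) also gave no gene that passed. Nearest were the sialic acid genes nanT (-2.53, SE 0.46) and nanC (-3.44, SE 0.68) and nrdG (-1.84, SE 0.36), for anaerobic ribonucleotide reduction, all at adjusted p = 0.472. The rpsA1 mutant alone had hdeD at 2.29 (SE 0.50) and nanC at -4.14 (SE 1.02), both at adjusted p = 1. Of 42 motility genes 0 passed (0 adjusted over the list alone) in the pooled comparison, with a median of 1.38 and a list adjusted p = 9.44e-07, or 0.825 with an estimated correlation. In rpsA1 the motility median was 2.88, at a list adjusted p = 9.30e-13, or 0.958 with an estimated correlation. This rests on 1 library, since the motility score was 4.25 and fliC 19883 CPM in rpsA1 chloramphenicol, against -0.547 and 402 CPM in the library labelled rpsA1 capreomycin. The edgeR test called 0 of 3865 genes in the pooled comparison, with 394 at an unadjusted p under 0.05, and 0 of 3927 for rpsA1, with 62, while DESeq2 called 23 and 0. In the pooled comparison 6 genes passed without the library labelled rpsA1 capreomycin (5.18 CPM for the 24 genes), 2 without the library labelled wild-type capreomycin 2000 replicate 2 (177 CPM), 93 without both and 22 within chloramphenicol. For rpsA1, 2 genes passed without the library labelled wild-type capreomycin 2000 replicate 2 and 89 without both. Without both, 23 of 42 motility genes rose in the pooled comparison (median 4.94) and 31 of 42 for rpsA1 (median 6.19), with a list adjusted p = 0.438 and 0.211 with an estimated correlation. Of other splits of the same 10 libraries, the one that called most genes, 1149, set rpsA1 with wild type against the truncations.

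The rpsAdelta6 mutant (2 libraries) was compared with wild type (4), a comparison that mixes the rpsA genotype with the strain background. The receptor gene pqqU rose by 5.86 (SE 0.60, adjusted p = 0.00355), inaA by 4.01 (SE 0.30, adjusted p = 0.00129), ybjC by 3.99 (SE 0.39) and the glucose dehydrogenase gene gcd by 3.79 (SE 0.52), and the capsule regulator gene rcsA by 5.14 (SE 1.09). The nitrite reductase genes nrfB (-6.38, SE 0.996) and nirB (-5.20, SE 1.05), the threonine gene tdcB (-6.20, SE 0.86) and the asparaginase gene ansB (-5.12, SE 0.85) fell. Of 21 oxidative stress genes 7 rose (8 adjusted over the list alone), such as acnA (3.05, SE 0.36), zwf (2.31, SE 0.31) and ahpF (1.25, SE 0.22), at a list adjusted p = 0.00217, or 0.868 with an estimated correlation. Of 76 amino acid biosynthesis genes 12 rose and 3 fell (13 and 3 adjusted over the list alone), among them argD (2.50, SE 0.20), aroH (2.41, SE 0.24) and argA (2.53, SE 0.31), at a list adjusted p = 0.0105, or 0.868 with an estimated correlation. The porin gene ompF fell by 2.82 (SE 0.30), tolC rose by 1.89 (SE 0.21), and the protease gene lon fell by 4.01 (SE 0.91, adjusted p = 0.0383). Of 74 anaerobic genes, a list drawn up after the data had been seen, 23 fell (34 adjusted over the list alone) at a list adjusted p = 2.54e-21, or 0.192 with an estimated correlation.

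The test for rpsAdelta6 called 411 of 3927 genes, 201 higher and 210 lower, and DESeq2 861. Counts without single libraries were 75 and 73 (first and second chloramphenicol), 267 (rpsA1 chloramphenicol), 58 (rpsAdelta6 chloramphenicol), 153 (first capreomycin 2000) and 268 (the library labelled rpsA1 capreomycin). The fits within 1 drug set 1 rpsAdelta6 library against 2 of wild type, with the spread from the wild-type pairs of both drugs. The calls of pqqU, inaA and ybjC held throughout. Within capreomycin those of nrfB (-4.86), tdcB (-6.11), nirB (-4.26), ansB (-4.31) and rcsA (4.22) ended, and within chloramphenicol those of tdcB (-6.27) and rcsA (6.71). Without rpsAdelta6 chloramphenicol the values of nrfB (-5.17, adjusted p = 0.102), tdcB (-6.14, adjusted p = 0.0785), nirB (-4.23, adjusted p = 0.109), ansB (-4.37, adjusted p = 0.0904), gcd (3.90, adjusted p = 0.0538) and rcsA (4.80, adjusted p = 0.128) no longer passed. The calls of nirB and rcsA also ended without the first chloramphenicol (-5.13 and 4.74), the second chloramphenicol (-5.15 and 4.66) or the first capreomycin library (-5.02 and 5.01). That of ansB ended without the first chloramphenicol library (-5.10), and that of rcsA without rpsAdelta6 capreomycin (5.52), rpsAdelta56 chloramphenicol (5.22) or rpsAdelta56 capreomycin (5.23). Without the libraries labelled wild-type capreomycin 2000 replicate 2 and rpsA1 capreomycin (177 and 5.18 CPM for the 24 genes), 13 of 18 heat shock genes rose and 1 fell. Of 42 motility genes 26 rose, and of 37 iron genes, a later list, 20 rose. Camera with an estimated correlation gave adjusted p = 0.577, 0.577 and 0.182. The level of fliC was 202 CPM in rpsAdelta6 chloramphenicol, near the 190 and 203 of wild type, and 12691 in rpsAdelta6 capreomycin.

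The rpsAdelta56 mutant (2 libraries) was compared with wild type (4), which likewise mixes the rpsA genotype with the strain background. The arginine genes argA and argD rose by 3.53 (SE 0.31, adjusted p = 0.00602) and 3.30 (SE 0.20, adjusted p = 0.00171), the protease gene pqqL by 4.02 (SE 0.53), and marA, a regulator of drug resistance, by 3.57 (SE 0.44). The genes cadB (-4.79, SE 1.18), tdcB (-4.50, SE 0.78), dcuC (-4.18, SE 0.80) and napA (-3.87, SE 0.89), for lysine, threonine, fumarate and nitrate use without oxygen, fell. Of 33 large subunit genes 8 rose (18 adjusted over the list alone), such as rpmB (2.53, SE 0.30) and rpmH (2.17, SE 0.30), and of 20 small subunit genes 5 rose (12 adjusted over the list alone), such as rpsF (1.69, SE 0.32) and rpsM (1.57, SE 0.31). Glycolysis had 6 of 17 lower (9 adjusted over the list alone), including pgk (-2.27, SE 0.39) and gapA (-1.59, SE 0.32), and 11 of 47 tryptophanase and sugar genes fell (16 adjusted over the list alone), including nagB (-2.18, SE 0.28) and treB (-2.31, SE 0.33). These lists passed at adjusted p = 3.21e-10, 2.19e-06, 2.10e-04 and 1.12e-04, each at adjusted p = 0.70 with an estimated correlation. Amino acid biosynthesis had 15 of 76 higher and 4 lower (19 and 9 adjusted over the list alone), with argG at 2.40 (SE 0.22), at a list adjusted p = 7.16e-04, or 0.832 with an estimated correlation. Of 74 anaerobic genes, a list drawn up after the data had been seen, 24 fell (45 adjusted over the list alone) at a list adjusted p = 3.91e-18, or 0.293 with an estimated correlation.

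The rpsAdelta56 test called 597 of 3927 genes, 262 higher and 335 lower, and DESeq2 1035. No gene passed without rpsAdelta56 chloramphenicol in the pooled fit, where argD was 3.29 (adjusted p = 0.0519), argA 3.83 (adjusted p = 0.0519), pqqL 2.81 and marA 2.81 (both at adjusted p = 0.0699). The count was 130 and 155 without the first and second chloramphenicol, 372 without the first capreomycin 2000 and 96 without rpsAdelta56 capreomycin, and 202 within capreomycin, of which 144 were among the 597. Within capreomycin argD was 3.17 and argA 3.67 (both at adjusted p = 0.0438). Without rpsAdelta56 capreomycin the calls of cadB (-4.40), tdcB (-4.93), dcuC (-3.88) and napA (-3.50) ended. Those of cadB (-4.79 and -4.17), dcuC (-4.06 and -4.03) and napA (-3.79 and -3.72) ended without the first and without the second chloramphenicol library. Without the first capreomycin 2000 library cadB (-4.99) and napA (-3.65) no longer passed, and napA did not pass without either rpsA1 library (-3.88 for both). Within capreomycin the calls of cadB (-4.46), tdcB (-4.13), dcuC (-3.98) and napA (-3.84) ended, and within chloramphenicol those of tdcB (-4.96), dcuC (-4.34) and napA (-3.90). Without the libraries labelled wild-type capreomycin 2000 replicate 2 and rpsA1 capreomycin (177 and 5.18 CPM for the 24 genes), 12 of 18 heat shock, 27 of 42 motility and 23 of 37 iron genes rose. The iron list was drawn up later. Camera with an estimated correlation gave adjusted p = 0.714, 0.714 and 0.216. Not every motility gene was raised, since fliC was at 154 and 206 CPM in rpsAdelta56. It was at 190 and 203 CPM in wild-type chloramphenicol and 95.6 in the first capreomycin 2000 library.

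Both truncations were compared with the same 4 wild-type libraries, so a share of their overlap comes from those libraries. They had 97 genes higher in both (13.4 by product of the counts), 134 lower in both (17.9) and 2 in opposite directions, with a Spearman correlation of 0.719. Simulated data without a genotype effect, drawn independently for each library, gave 0 shared calls and a correlation of 0.29. With the controls split between the mutants the correlations were 0.637 and 0.70, with 0 genes called in both. Those split fits had too few residual degrees of freedom for the 0 calls to say much. The covariance of 1.05 exceeded the simulated 0.136 by 0.917. This excess cannot be told apart from a background that the truncation strains share. Between the truncations, hemB (-3.21, SE 0.30, adjusted p = 0.0229), inaA (-3.08, SE 0.37), yadG (-2.61, SE 0.32), mdaB (-2.38, SE 0.26) and lpxL (-2.38, SE 0.25) were lower in rpsAdelta56, with hemB, for heme synthesis, at 1154 and 870 CPM in rpsAdelta6 and 123 and 88.8 in rpsAdelta56. Of 33 large subunit genes 0 passed (2 higher adjusted over the list alone), with a median of 0.972 and a list adjusted p = 2.79e-09, or 0.732 with an estimated correlation. The test called 6 of 3927 genes and DESeq2 213, and 10 passed with DESeq2 size factors and 18 without a filter. No gene passed without the first chloramphenicol (hemB -3.21, adjusted p = 0.107), the second chloramphenicol (hemB -3.21, adjusted p = 0.0941), rpsA1 chloramphenicol (hemB -3.21, adjusted p = 0.063), rpsAdelta6 chloramphenicol (hemB -3.05, adjusted p = 0.0575), rpsAdelta56 chloramphenicol (hemB -3.47, adjusted p = 0.133), the library labelled rpsA1 capreomycin (hemB -3.21, adjusted p = 0.0604) or rpsAdelta56 capreomycin (hemB -2.94, adjusted p = 0.246). Without the first capreomycin 2000 library 1 gene passed, and without the 2 doubted libraries 13.

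The capreomycin effect was not shown to differ between the mutants and wild type for any gene. The nearest were the hibernation genes elaB (3.02, SE 0.65) and sra (1.99, SE 0.41) above and melR (-2.69, SE 0.47) and lgoR (-2.66, SE 0.44) below, all at adjusted p = 0.553. Of 8 hibernation genes 0 passed (4 higher adjusted over the list alone), with a median of 1.36 and a list adjusted p = 1.23e-04, or 0.428 with an estimated correlation. The TCA cycle had a median of -1.98 with 0 of 17 passing (5 lower adjusted over the list alone), at 1.08e-08, or an adjusted p = 0.438 with an estimated correlation. Aerobic respiration and lactate genes, a list drawn up later, had a median of -3.50 with none passing (6 lower adjusted over the list alone), and passed at adjusted p = 6.72e-18 and at 0.0307 with an estimated correlation. As the list was chosen with these libraries in view, its passing is no independent evidence. Without the libraries labelled wild-type capreomycin 2000 replicate 2 and rpsA1 capreomycin (177 and 5.18 CPM for the 24 genes), the median of that list was -2.19, and it passed at adjusted p = 8.04e-15 but had an adjusted p = 0.124 with an estimated correlation. The hibernation and TCA cycle medians were then 1.45 and -1.98, at list adjusted p = 0.0112 and 3.96e-08, and adjusted p = 0.472 and 0.611 with an estimated correlation. No gene passed without these libraries either. The edgeR test called 0 genes with 333 at an unadjusted p under 0.05, and DESeq2 called 35. In simulated data the test recovered 0% of 8-fold differences. For rpsA the value was -0.37 (SE 1.07, adjusted p = 0.977), 0.09 without rpsAdelta6 chloramphenicol and 0.75 without the first capreomycin 2000 library.

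The irCLIP signal exceeded footprints mostly on genes with few footprints (4 libraries each, drug as a term). The genes yacH (6.75, SE 0.35), ugpA (6.52, SE 0.32) and cusA (5.26, SE 0.26) were higher, with yacH at 0.516 (SD 0.039) CPM in chloramphenicol footprints and 38.5 (SD 2.93) in irCLIP on the scaling shared by both assays. The small protein gene yobF was higher by 5.36 (SE 0.60, adjusted p = 2.72e-04). Among genes with many footprints, those called higher were secY (2.94, SE 0.71, adjusted p = 0.0089), rpsA (1.94, SE 0.63, adjusted p = 0.0301), glpF (1.48, SE 0.32), atpB (1.05, SE 0.28) and locus b4600 (0.76, SE 0.21), which are 5 of 425 in the top decile, a group singled out after its values were seen. The genes secY, glpF and atpB encode the translocon channel, the glycerol channel and a membrane subunit of ATP synthase. Mean levels on the shared scaling went from 1327 CPM in footprints to 9439 in irCLIP for secY and from 7449 to 27498 for rpsA. TMM factors were 1.9-fold higher in irCLIP than in footprints, so levels scaled within each assay differ more. The genes napB (-5.58, SE 1.16), garR (-4.78, SE 0.92) and ftnA (-3.88, SE 0.42) were lower. Of 17 glycolysis genes 15 were lower (16 adjusted over the list alone), such as eno (-2.19, SE 0.31), and of 23 aminoacyl-tRNA synthetase genes 20 were lower (21 adjusted over the list alone), such as tyrS (-1.69, SE 0.18) and argS (-2.04, SE 0.23). Secretion genes had 14 of 17 lower and 1, secY, higher (15 and 1 adjusted over the list alone). These lists passed at adjusted p = 3.89e-05, 3.60e-06 and 0.00109, and had an adjusted p = 0.491, 0.491 and 0.215 with an estimated correlation. Of all 4242 genes 1171 were lower, and the log2 fold change had a Spearman correlation of -0.778 with the footprint level. The lower values of these lists were not set apart from that dependence on footprint level.

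The test of irCLIP against footprints called 2573 of 4242 genes, 1402 higher and 1171 lower. Of 34 splits of the 8 libraries, only the labelled one called any, and the highest other called 0. The irCLIP libraries had 235 to 300 CPM for the 24 genes from yahI to mhpE, above the wild-type footprints. They had 1092 to 3583 CPM for lacZ, within the wild-type range of 694 to 4152. Effects of a difference of strain between the assays therefore cannot be told apart from effects of the assay. The call of rpsA ended without the first chloramphenicol footprint library (1.66, adjusted p = 0.107), the second (1.75, adjusted p = 0.10), the second chloramphenicol irCLIP library (1.42, adjusted p = 0.0605) or the second capreomycin irCLIP library (2.06, adjusted p = 0.0596). For the 1402 genes called higher, 1278 (91.2%) lay below the median footprint level.

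**Figure D3:**
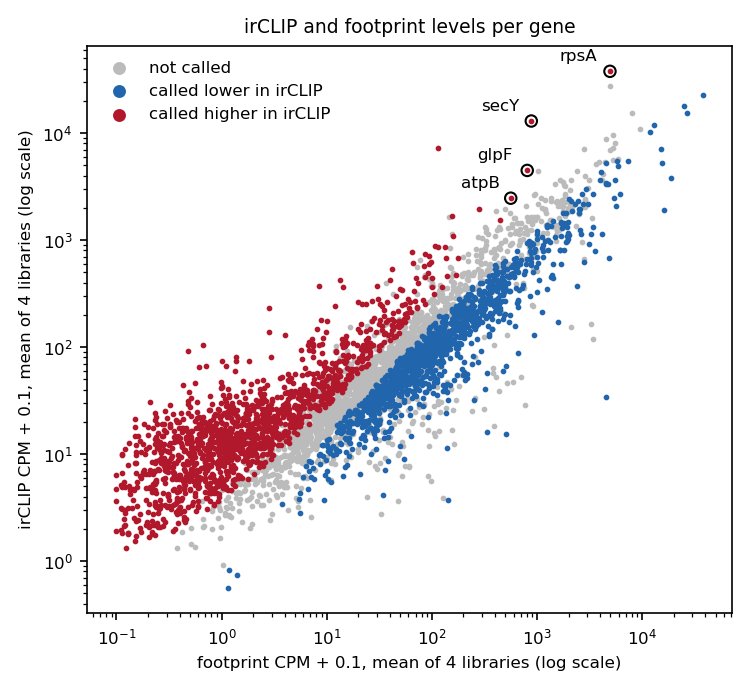
Mean irCLIP level against mean footprint level per gene, 4 libraries each, scaled within each assay, on log scales. Genes called higher and lower in irCLIP are coloured, and rpsA, secY, glpF and atpB are circled.

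Within irCLIP, capreomycin against chloramphenicol (2 libraries each) gave no gene that passed. The largest by p were the methyltransferase gene rlmC (2.14, SE 0.25), wrbA (1.99, SE 0.26) and bssS (1.68, SE 0.22) above and ygaV (-1.63, SE 0.29), accB (-1.29, SE 0.23) and rnb (-1.13, SE 0.22) below, all at adjusted p = 0.453. Of 23 aminoacyl-tRNA synthetase genes 0 passed (0 adjusted over the list alone), with a median of -0.606 and a list adjusted p = 1.90e-06, or 0.547 with an estimated correlation. Leader peptides had a median of 0.63 with none passing (2 higher adjusted over the list alone), at a list adjusted p = 0.00916, or 0.547 with an estimated correlation. For rpsA the value was -0.71 (SE 0.55, adjusted p = 0.655). The edgeR test called 0 of 4117 genes with 440 at an unadjusted p under 0.05, and DESeq2 called 8. With the replicate number as a block, 391 genes passed. That pairing rests on the number alone, over 2 pairs, with a correlation of deviations of 0.523. Without the second chloramphenicol irCLIP library 26 genes passed.

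The drug change of irCLIP differed from that of footprints for genes such as cadA and lldP. The interaction, irCLIP change minus footprint change, was positive for cadA (8.23, SE 0.73, adjusted p = 0.00372), narH (7.99, SE 0.88) and tdcD (7.94, SE 0.65). Their footprints fell with capreomycin, while irCLIP levels in chloramphenicol and capreomycin were 28.2 (SD 2.93) and 29.0 (SD 6.70) CPM for cadA and 37 (SD 11) and 67 (SD 46) for narH. The positive values of cadA and narH thus rest mainly on the footprint change. Background reads may hold irCLIP at such levels, in which case it could not show a fall. The interaction was negative for fhuF (-7.24, SE 1.51), lldP (-5.83, SE 0.60), mqo (-5.32, SE 0.51) and cyoB (-5.17, SE 0.55). Footprints of lldP, mqo and cyoB rose with capreomycin in the same wild-type libraries, while the irCLIP drug comparison called no gene. The negative values of lldP, mqo and cyoB thus also rest mainly on the footprint change. Of 25 RpoS genes 6 were positive (20 adjusted over the list alone), including wrbA (5.93, SE 0.65) and hdeA (2.33, SE 0.32), and in the TCA cycle 7 of 17 were negative and 1 positive (13 and 1 adjusted over the list alone), including sdhB (-4.28, SE 0.32). These passed at adjusted p = 1.33e-10 and 3.38e-09, both at adjusted p = 0.291 with an estimated correlation. Of 80 anaerobic genes, a later list, 39 were positive (57 adjusted over the list alone) at a list adjusted p = 9.82e-37, or 0.0628 with an estimated correlation. Of 37 iron genes, also a later list, 8 were negative (27 adjusted over the list alone) at 6.54e-15, or an adjusted p = 0.174 with an estimated correlation. The iron median was -2.15 without the library labelled wild-type capreomycin 2000 replicate 2 (177 CPM for the 24 genes), which left 1 capreomycin footprint library. The motility and heat shock medians were -4.95 and -2.48 with none passing (0 adjusted over the list alone), and 0.0168 and 0.257 without that library. Aerobic respiration and lactate genes, a later list, had 15 of 35 negative (19 adjusted over the list alone) at adjusted p = 2.40e-20, and 0.00165 with an estimated correlation. That list was chosen after these footprints had been seen, so its passing is no independent evidence. The test called 331 of 4265 genes, 211 positive and 120 negative, and DESeq2 640. Counts without single libraries were 102 and 70 (first and second chloramphenicol footprints), 901 (first capreomycin footprints), 119 and 162 (chloramphenicol irCLIP) and 119 and 91 (capreomycin irCLIP). The call of fhuF ended without the first and second chloramphenicol footprints (-6.94 and -7.61), the first and second chloramphenicol irCLIP (-6.85 and -7.51) and the first and second capreomycin irCLIP libraries (-7.71 and -6.88).

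Asparagine, proline(CGG) and threonine(CGT) tRNAs made up a larger share of RNC tRNA than of input, and the 4 serine tRNAs a smaller one. The share of tRNA-Asn(GTT) was 7.25% in RNC1 and 10.3% in RNC2 against 1.62% in input, which is 4.48-fold and 6.38-fold. For tRNA-Pro(CGG) the shares were 6.19% and 6.89% against 1.78%, and a tRNA-Thr(CGT), trna5-ThrCGT, had 1.62% and 1.45% against 0.279%. The counterpart trna6-ThrCGT was higher by 4.01-fold and 4.79-fold and tRNA-Leu(TAA) by 2.39-fold and 4.23-fold, and tRNA-Trp(CCA) by 1.62-fold and 3.11-fold. Other threonine and proline isoacceptors went both ways. The share of trna43-ThrTGT was higher by 2.14-fold and 2.71-fold, and lower shares had RNC to input ratios of 0.367 and 0.37 for trna59-ThrGGT, 0.836 and 0.748 for tRNA-Pro(TGG) and 0.702 and 0.55 for tRNA-Pro(GGG). The 4 serine tRNAs summed to 1.39% and 1.8% against 5.50%, with tRNA-Ser(TGA) lower by 5.43-fold and 2.87-fold, tRNA-Ser(GGA) by 3.36-fold and 2.93-fold and tRNA-Ser(GCT) by 3.21-fold and 3.14-fold. Shares of tRNA-Ala(GGC) and trna38-LeuCAG were lower by 2.81-fold and 4-fold and by 2.92-fold and 2.99-fold. The RNC libraries parted on tRNA-Ile(GAT), at 9.79% and 4.6% against 6.06%, and on trna46-ThrGGT, at 2.63-fold and 0.891-fold. With 1 residual degree of freedom edgeR called 0 of 50 tRNAs, with 16 at an unadjusted p under 0.05 and a smallest adjusted p = 0.0593, and DESeq2 called 20, 10 in each direction. The labels do not say whether RNC1 and RNC2 are replicates of 1 preparation, and the median of all tRNAs was -0.192 with TMM and -0.0526 with DESeq2 size factors.

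**Figure D4:**
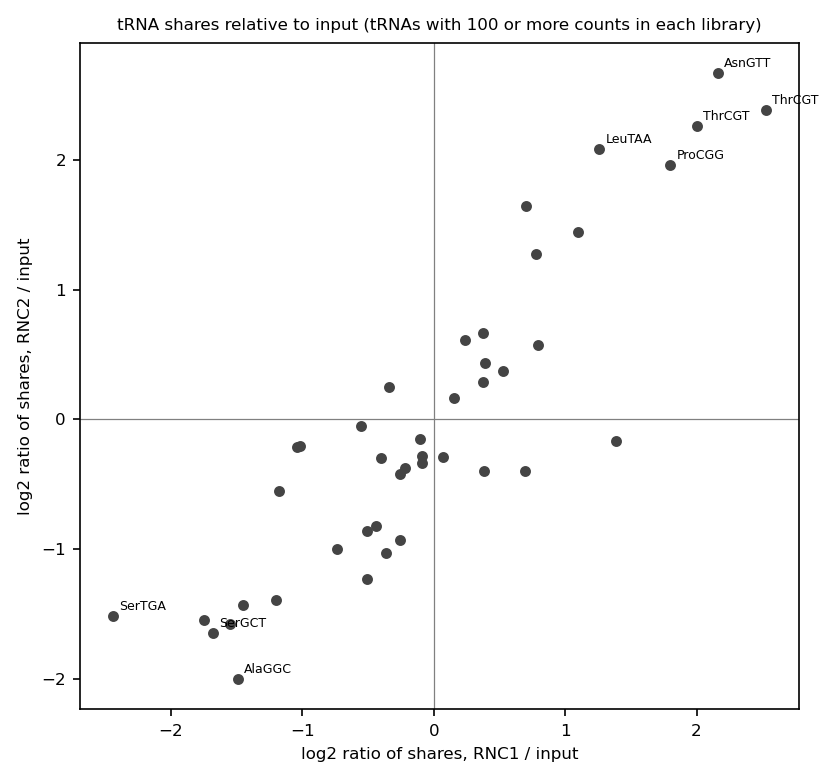
Log2 ratios of tRNA shares in RNC1 and RNC2 relative to input, for tRNAs with at least 100 counts in each library.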

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

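The tests on the 24 genes and on the anaerobic scores, the test of background for rpsA and the splits of the 2 mutant comparisons were chosen only after the result was seen. A difference between assays under the same drug contrast marked 331 genes, by an edgeR interaction test of irCLIP and footprints. The named genes with positive values were cadA (8.23), narH (7.99), tdcD (7.94), nirC (7.86), dmsC (7.60), cadB (7.39), tdcC (7.34) and tdcG (7.22). Those with negative values were fhuF (-7.24), fepD (-6.11), lldP (-5.83), fhuA (-5.79), bfd (-5.52), lldR (-5.35), mqo (-5.32) and cyoB (-5.17). As the irCLIP drug comparison called no gene in the main fit, these values do not show that irCLIP itself changed. Whether the strains of the assays differ stays open, since irCLIP had 235 to 300 CPM for the 24 genes from yahI to mhpE and 1092 to 3583 for lacZ, within the wild-type footprint range.

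The 24 genes from yahI to mhpE went against the labels of 2 libraries. An exchange of the labels wild-type capreomycin 2000 replicate 2 and rpsA1 capreomycin may be the cause, since the second had 5.18 CPM, although this stays above the highest wild-type value of 1.14. Over all genes, the library labelled rpsA1 capreomycin had a Spearman correlation of 0.973 with wild-type capreomycin 2000 replicate 1, against 0.939 for the labelled replicates. The level of fliC was 19957 CPM in the library labelled replicate 2, 19883 in rpsA1 chloramphenicol and 402 in the library labelled rpsA1 capreomycin. High fliC does not mark rpsA1 alone, since it was 12691 CPM in rpsAdelta6 capreomycin and 202 in rpsAdelta6 chloramphenicol. Induction of the genes by capreomycin is argued against by the other wild-type libraries with that drug, at 0.746 CPM (2000, replicate 1) and 0.0631 (200). A small admixture of another library is argued against by lacZ, at 115 CPM in the library labelled wild-type capreomycin 2000 replicate 2, and an exchange stays open.

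Anaerobic genes split the footprint libraries by neither drug nor genotype alone. Depth as the cause is argued against, because the gap in score between 3 and 7 libraries was 1.97 and stayed 1.96 after thinning each library to 1300311 counts. Capreomycin as the whole cause is argued against by the score of -1.64 in a truncation library in chloramphenicol, and truncation as the whole cause by the -0.846 in a capreomycin library not labelled as one. A joint effect of drug and truncation remains possible, and so does an unlabelled difference in growth or harvest, on which 0 labels give a batch, day or culture.

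Genes with few footprints were highest in irCLIP relative to footprints. Background reads that scale with gene length could be the cause for these genes, as the Spearman correlation of irCLIP level with length was 0.813 over the 500 genes with the fewest footprints, against 0.298 for footprints and -0.0334 in irCLIP over the 500 with the most. For rpsA, at 1.94 with footprint rank 25 of 4242, both values were known when this test was chosen, so it only restates the enrichment. By its rank rpsA is among the 500 genes with the most footprints, over which irCLIP level did not follow length. Its call also ended without some single libraries. Whether the remaining signal follows binding of S1 stays open, because no library without crosslinking was used here.

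For irCLIP against footprints 1 of 34 splits, the labelled one, reached 2573 genes and the highest other reached 0. Every other split mixes the assays within its groups, which widens the spread. The splits therefore show that the assays differ as a whole and do not bear on the calls of single genes. For the mutants against wild type the labelled count was 0, which all 100 of 100 splits reach by construction, so they say nothing on chance. The highest other split called 1149 genes. It set wild type and rpsA1 against the truncations and points to a structure of the samples other than mutant against wild type. For capreomycin against chloramphenicol in the mutants 10 of 10 splits were too few to judge, with a real value of 0 and a highest other of 0.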

How the results depend on the processing

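Of the named genes under all alternatives, 1569 values kept direction and side of the threshold, 374 no longer passed, 74 newly passed and 8 changed sign. The counts for irCLIP against footprints stayed within 1.5 times of 2573 throughout. The cause was not tested for the changes below, except where it is given.

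With DESeq2 in place of edgeR the counts were 1138 (wild-type capreomycin 2000 against chloramphenicol), 120 (the same in mutants), 23 (mutants against wild type), 861 (rpsAdelta6), 1035 (rpsAdelta56), 213 (between the truncations), 35 (mutant by drug), 185 (chloramphenicol against no drug), 414 (capreomycin 2000 against no drug), 8 (irCLIP drug change), 640 (irCLIP by drug) and 20 (tRNA). Between the truncations 10 genes passed with DESeq2 size factors and 18 without a filter, against 6.

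Leaving out 1 library at a time gave these ranges of calls: 0 to 1893 for wild-type capreomycin 2000 against chloramphenicol, 0 to 57 for the same in mutants, 0 to 6 for mutants against wild type, 0 to 2 for rpsA1, 58 to 496 for rpsAdelta6, 0 to 793 for rpsAdelta56 and 0 to 7 between the truncations. They were 0 to 1531 for chloramphenicol against no drug, 0 to 2015 for capreomycin 2000 against no drug, 0 to 1809 against viomycin 2000 and 0 to 1889 against 200, 0 to 26 for the irCLIP drug change and 70 to 901 for irCLIP by drug. A group left with 1 library was assumed to vary like the others. The value of rpsA changed sign in 5 such ranges and 1 other setting: -0.11 to 0.71 for rpsAdelta56 against wild type (-0.02 without the second capreomycin 2000 library, -0.19 within capreomycin), -1.07 to 0.75 for mutant by drug (0.09 without rpsAdelta6 chloramphenicol), -1.01 to 0.68 against no drug, -0.61 to 1.08 against viomycin 2000 and -0.0135 to 1.67 against 200.

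Alternatives added after seeing the data left out the 2 doubted libraries, which gave 57 calls for the drug in mutants, 93 for mutants against wild type, 89 for rpsA1 and 13 between the truncations. In the alternatives fixed beforehand that kept 1 drug, 22 genes passed within chloramphenicol for mutants against wild type and 777 for rpsAdelta6, and within capreomycin 60 for rpsAdelta6 and 202 for rpsAdelta56.

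With a replicate block, which pairs libraries by number, 25 genes passed for wild-type capreomycin 2000 against chloramphenicol, 391 for the irCLIP drug change and 182 for irCLIP by drug. The pairing rests on the number alone, over 2 pairs, and the correlation of deviations was -0.0791 in footprints and 0.523 in irCLIP.

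With at least 1000 counts the single-library comparisons kept 454 (capreomycin 200), 250 (viomycin 200), 375 (viomycin 2000), 435 (spectinomycin 200), 68 (spectinomycin 2000), 603 (blasticidin) and 239 (linezolid) genes, 276 and 224 between doses of viomycin and spectinomycin, 102 between capreomycin and viomycin 200, and 13 and 314 between replicate libraries of chloramphenicol and capreomycin 2000, since fewer genes are compared by construction. With an estimated correlation 0 of the 23 fixed gene lists passed in any of 15 comparisons. The tRNA comparison without single libraries was not run as a test, for lack of residual degrees of freedom, and alternatives on sequence features and on normalized values were not run. Depth limits the spectinomycin 200 library (1300311 counts) and RNC1 (35593).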

Other observations

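Compared without a replicate and with the library without drug, the nitrite reductase gene nirB was lower by 29.3-fold in capreomycin 200, the nitrate transport gene narK by 25.8-fold in viomycin 200 and the nitrite reductase gene nirD by 218-fold in blasticidin. Ribosome hibernation genes had median log2 ratios to no drug of 1.28 in capreomycin 200, 2.68 in spectinomycin 200, 3.11 in blasticidin and 0.0981 in viomycin 200. The medians were -1.34 in viomycin 2000, -0.974 in linezolid and -0.574 in spectinomycin 2000.

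The small protein gene yobF held 60.2 CPM in chloramphenicol footprints and 278 in capreomycin 2000 footprints, and 5322 and 5300 CPM in irCLIP, on the scaling shared by both assays. The maltose gene malK reached 3919 CPM in the rpsA1 chloramphenicol library and 3924 in the library labelled wild-type capreomycin 2000 replicate 2. The anaerobic score was -1.04 and -0.232 in chloramphenicol irCLIP and -0.302 and 0.375 in capreomycin irCLIP, whose levels were scaled within irCLIP.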
